A study of Mus musculus with 6 samples.

How the data were processed

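The series measured gene expression by RNA sequencing in hepatocytes taken from chemically induced liver tumours of male mice. Per the labels' protocols, mice received a single intraperitoneal dose of the liver carcinogen diethylnitrosamine (DEN) of 90 μg per g at 6 weeks of age. A pause of 3 weeks followed, and then a diet with 0.05% phenobarbital (PB), a liver tumour promoter, for 27 weeks. Primary hepatocytes were isolated from the tumours 30 weeks after the injection. RNA was extracted with Trizol, and 1 μg of total RNA entered a standard Illumina library. The 6 libraries fell into 2 groups of 3 by the genotype in their titles. Ripply1 F/F mice carried loxP sites around exons 1 to 3 of Ripply1. Ripply1 ΔHep mice carried the same alleles together with Alb-Cre, a recombinase transgene active in hepatocytes. Nothing in the labels says that the replicates of a group came from separate animals, so the p-values measure the spread between these samples, which may in part be technical.

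The authors deposited 1 table of raw read counts per gene symbol, with a column for each library and 18260 genes. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with HISAT2 2.0.4. The counting program, the gene annotation, the strand setting and any filter on genes are not given in the sources used here. Reads shared by near-identical genes, by overlapping genes or by antisense partners can therefore not be assigned with certainty, and values of such genes are uncertain. Mitochondrially encoded mRNAs and Tbx19 were not analysed here.

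Total counts per library ran from 27772849 to 35894395. At this depth 1 CPM, the usual unit of counts scaled to library size, stood for between 26.67 and 37.87 counts, so the counting error of a gene at 1 CPM was of the same order as the common biological coefficient of variation, 21.5%. For genes below that level, such as Ripply1, counting error dominates. Confidence intervals of counts rest on counts pooled over the libraries of a group, so they leave out the spread between samples and cover counting error only. Reads were not tied to single molecules, so even the counting error may be understated. Replicates were compared before averaging. A chi-square statistic of the counts of each pair of libraries within a group, divided by its degrees of freedom, ranged from 17.92 to 106.2, far above the value near 1 that repeated counting of the same library would give, so all 6 were kept as separate samples.

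The comparison of ΔHep with F/F used edgeR 4.0.16 in R 4.3.3 on the deposited counts. Low genes were removed with filterByExpr, which kept 14552 genes, with a minimum count of 10 and a minimum total of 15. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values are on the scaled sizes. Genes were tested two-sided with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are ΔHep over F/F on the log2 scale, and the standard error (SE) of each is its size divided by the square root of F. Ripply1 fell below the filter, so its counts, its CPM and an exact two-sided permutation test of its CPM are given, with a 95% exact interval for the ratio of pooled counts.

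Before the data were examined, 33 gene lists were fixed from textbook knowledge. The 4 primary lists held hepatic β-catenin targets, stemness and liver progenitor genes, mature hepatocyte genes, and cell cycle and mitosis genes. Secondary lists covered RIPPLY and T-box genes, periportal and phenobarbital-induced hepatocyte genes, sex-biased liver genes, and lipid, cholesterol and glucose metabolism. They also covered inflammation, interferon response, p53, oxidative stress, endoplasmic reticulum stress, and Notch and Hippo pathway genes with their targets. Epithelial-mesenchymal transition, imprinted and oncofetal genes, immediate early genes and mitochondrially encoded mRNAs had lists too. Others held markers of cell types that a hepatocyte isolation can carry along: stellate cells and fibroblasts, macrophages, endothelial cells, T and NK cells, B and plasma cells, dendritic cells, neutrophils, cholangiocytes, erythroid cells and pancreatic acinar cells. Each list was tested with camera in limma 3.58.1, which compares its genes with all other genes, at a preset correlation between genes of 0.01, and adjusted over the 32 lists that had a tested member. The same test with a correlation estimated from the data is given beside each call. For the members of a list, p-values were also adjusted over the list alone.

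The genes named in the text followed a rule set at the same time. It took Ripply1 and Tbx19, and the 12 genes with the highest and the 12 with the lowest fold change among those past the threshold with ranges that did not overlap and a higher group mean of at least 1 CPM. Symbols of predicted genes and of receptor segments were left out, which concerned 6 genes past the threshold. From each list up to 4 members past the threshold were taken, and from a list with none the 2 members of highest mean CPM. Some genes that the rule takes are not reported here. Members of a list that are named beyond this rule were chosen after their values were seen. Gene positions are 1-based on GRCm38, the assembly named mm10 in the notes, from the GENCODE annotation supplied with it, in which all 94 named genes had a record.

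The edgeR step was tested on simulated data drawn from the means and sizes of the real libraries. The changed genes all had a mean of at least 1 CPM, the spread of each gene followed the trend over expression, and no library was set apart. Of 14552 simulated genes 14311 passed the filter, and 200 were changed. The test recovered 71% of those changed 2-fold and 96% of those changed 4-fold, with 4 false calls among 171. These rates do not cover genes at lower levels or data in which single libraries move the count. A simulated 2-fold rise of the stemness list was called, and 0 of the 28 lists that shared no member with it were called. Genes were simulated independently of each other, so this gives no rate of false list calls for lists whose members vary together. Alternatives fixed in advance, except that fry and the left-out libraries were added for the secondary lists after the data were seen, were another scaling, library totals without scaling, other filters on low counts, robust moderation, a block on the replicate number, each library left out in turn, a fold threshold, DESeq2 1.42.0, limma-voom, and for lists the estimated correlation and fry, a rotation test. Counts of list members at an unadjusted p below 0.05, with DESeq2 and with limma-voom, and list medians without single libraries were added after the data were seen. Low genes were filtered anew in each fit without a library, and DESeq2 took all genes. List medians from such fits, and list tests without a library, can therefore cover other members than the main fit.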

Results

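The series asked what loss of Ripply1, a transcriptional co-repressor that acts on T-box factors, does to tumour hepatocytes; its title names cancer cell stemness, TBX19 and tumours with mutated CTNNB1, the gene of β-catenin. Expression was measured in 3 Ripply1 F/F and 3 Ripply1 ΔHep libraries of hepatocytes from DEN/PB-induced mouse liver tumours. Total counts were 27772849, 32199523 and 29471930 in F/F replicates 1, 2 and 3 and 33565923, 31484308 and 35894395 in ΔHep replicates 1, 2 and 3. Between 17219 and 17797 genes had at least 1 count. Albumin alone took 7.292% to 10.05% of the counts of a library.

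Ripply1 was scarce in F/F hepatocytes and close to the floor in ΔHep hepatocytes. The 3 F/F libraries held 13, 8 and 12 counts and the 3 ΔHep libraries 1, 1 and 2. Mean expression was 0.389 ± 0.124 CPM (SD, n = 3) in F/F and 0.0377 ± 0.0131 CPM (SD, n = 3) in ΔHep. Pooled counts of 33 and 4 gave a ratio of F/F over ΔHep of 9.93, with an exact 95% interval from 3.53 to 38.6. The groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. With all genes kept, edgeR gave a log2 fold change of -3.23 (SE 0.80, adjusted p = 0.0756), which did not pass, while DESeq2 gave -3.36 with an adjusted p of 0.035. Ripply1 lies on the minus strand of chromosome X from 139779549 to 139782353. Exons 1 to 3 of its annotated transcript, the part flanked by loxP sites, span 139780491 to 139782353, and exon 4, from 139779549 to 139780012, lies outside it, so a count over the whole gene can include reads from a deleted allele.

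**Figure D1:**
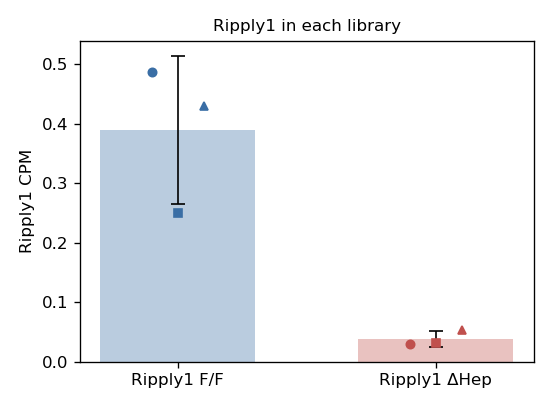
Ripply1 expression in CPM on TMM-scaled library sizes (vertical axis) in Ripply1 F/F and Ripply1 ΔHep libraries; points are single libraries, bars are group means and error bars are SDs (n = 3). The F/F libraries lie between 0.249 and 0.487 CPM and the ΔHep libraries between 0.0296 and 0.0528 CPM.

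Of 14552 genes tested, 244 differed between the genotypes, 220 higher and 24 lower in ΔHep. Gldn, which encodes gliomedin, an extracellular matrix protein, rose from 0.246 ± 0.118 to 18.6 ± 8.40 CPM (SD, n = 3 each), a log2 fold change of 6.23 (SE 0.51, adjusted p = 0.00806). Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.436 ± 0.0531 to 4.75 ± 1.13 CPM, a log2 fold change of 3.43 (SE 0.30, adjusted p = 0.0105). Serpine2, a secreted inhibitor of serine proteases, fell from 28.4 ± 6.28 to 4.82 ± 0.343 CPM, a log2 fold change of -2.56 (SE 0.19, adjusted p = 0.00792). Albumin, the main secreted protein of hepatocytes, stood at 84517 and 84890 CPM, with a log2 fold change of 0.01 (SE 0.20, adjusted p = 0.99). Gldn lies on chromosome 9 (54286486 to 54341786, plus strand), Gpnmb on chromosome 6 (49036546 to 49070929, plus strand) and Serpine2 on chromosome 1 (79794197 to 79861180, minus strand).

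Among the other genes with the highest fold changes, Shc2, an adaptor of receptor tyrosine kinases, rose by a log2 value of 6.13 (SE 0.70), to 3.51 ± 2.03 CPM. Rasal1, a GTPase-activating protein of Ras, rose by 4.33 (SE 0.60), and Ly6d, a surface protein, by 4.26 (SE 0.66), to 8.38 ± 4.44 CPM. Gucy2c, the intestinal guanylate cyclase receptor, rose by 3.92, Slfn4, an interferon-inducible Schlafen gene of myeloid cells, by 3.84, and Sema3g, a secreted semaphorin, by 3.63. Mmp12, the macrophage metalloelastase, rose by 3.31, Ncapg, a condensin subunit, by 3.22, Myo5c, an epithelial myosin, by 3.12, and Sdk2, a cell adhesion molecule, by 3.03. Adjusted p for these 10 genes lay between 0.0329 and 0.0469. All 10 had a mean below 0.5 CPM in the F/F libraries, so the size of their fold changes is less exact than its sign. It moved to 5.25 for Ly6d without F/F replicate 1, to 4.88 for Slfn4 and 3.85 for Myo5c without F/F replicate 2, to 4.11 for Ncapg and 3.65 for Sdk2 without F/F replicate 3, and to 2.65 for Mmp12 without ΔHep replicate 3. Among genes that fell, Trhde, a peptidase that degrades thyrotropin-releasing hormone, changed by -3.98 (SE 0.63; -5.15 without ΔHep replicate 2) and the homeobox gene Irx1 by -3.49 (SE 0.50). Mapk15, an atypical MAP kinase, changed by -2.25, Nxpe2 by -2.02, the kinase Aatk by -1.61 and Plekhb1 by -1.55. Hao1, the peroxisomal glycolate oxidase, went from 378 ± 26.7 to 234 ± 27.2 CPM (log2 fold change -0.69, SE 0.13) and Glo1, the glyoxalase that clears methylglyoxal, from 277 ± 9.55 to 173 ± 14.4 CPM (log2 fold change -0.68, SE 0.11). Tmem19 changed by -0.93, Celf2, an RNA-binding protein, by -0.90 and Dpy19l3 by -1.03.

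**Figure D2:**
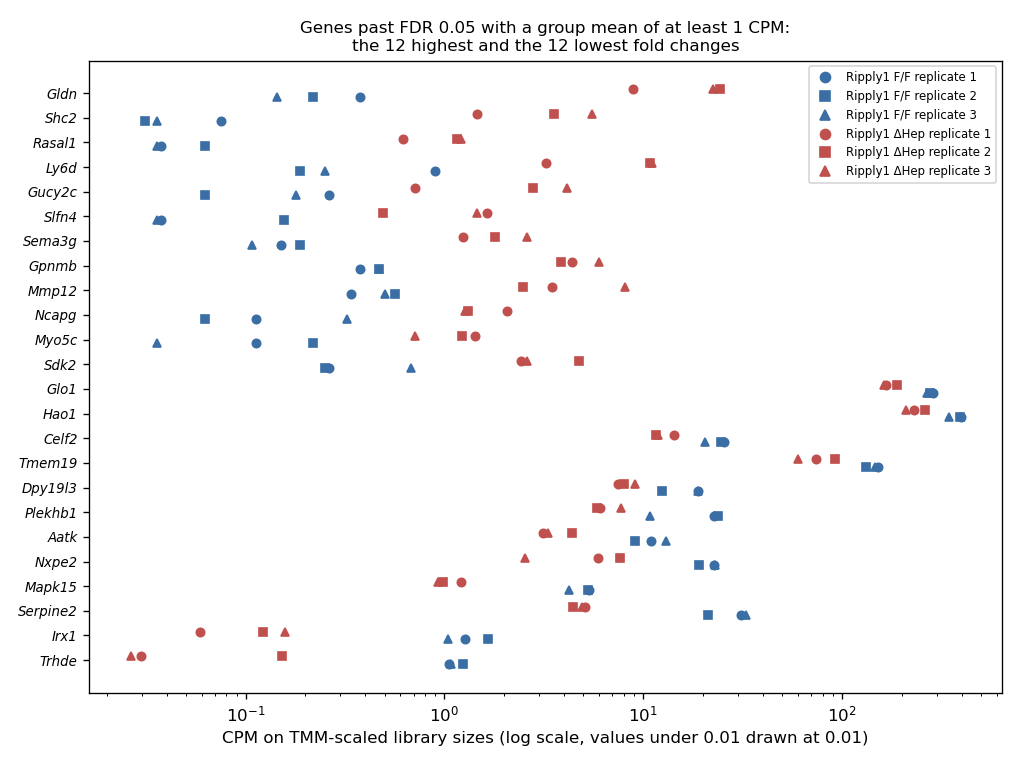
Expression in CPM on TMM-scaled library sizes (horizontal axis, log scale) of the 12 genes with the highest and the 12 with the lowest fold change among those past the threshold that reached 1 CPM in a group mean, predicted genes left out; each point is a library, coloured by genotype and shaped by replicate. Ranges of the F/F and ΔHep libraries that do not overlap were a condition for the genes shown. They run from Gldn (0.246 CPM in F/F against 18.6 CPM in ΔHep) to Trhde (1.12 against 0.0697 CPM).

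In all 244 genes the ranges of the groups did not overlap, as they did not in 27.1% of all tested genes, against 10% by chance. At an unadjusted p below 0.05 there were 3069 genes, 2054 higher and 1015 lower. The count of 244 depended on single libraries: without F/F replicate 1, 2 or 3 it was 2, 1 or 1246, and without ΔHep replicate 1, 2 or 3 it was 215, 4 or 5. DESeq2 called 1304 genes and limma-voom 88. Library totals without scaling gave 644 genes, 615 higher and 29 lower. Serpine2 passed in each of these fits, and all 244 genes kept their direction in them.

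Of 32 gene lists with a tested member, 16 passed the list test, 13 towards higher and 3 towards lower values in ΔHep, while 0 passed with an estimated correlation. With fry, which tests a list against no change and not against other genes, 9 passed. Stemness and progenitor genes were higher in ΔHep as a group. Of 21 tested members 4 rose and 17 did not pass, with 11 higher when adjusted over the list alone. There were 18 positive fold changes and a median log2 fold change of 0.75. The median was 1.28 without F/F replicate 3 and 1.13 with DESeq2 on all libraries. Members kept in those fits can differ from the 21, so neither move can be credited to the library or the method alone. The list test gave an adjusted p of 3.29e-07, and an adjusted p = 0.231 with an estimated correlation. Prom1, the surface antigen CD133, rose from 0.799 ± 0.0443 to 4.68 ± 2.34 CPM (log2 fold change 2.54, SE 0.38, adjusted p = 0.0329). Krt19 and Krt7, keratins of bile duct and progenitor cells, rose by 2.47 (SE 0.40, adjusted p = 0.0346) and 1.95 (SE 0.37, adjusted p = 0.0449), and Cd24a, a surface sialoglycoprotein, by 1.59 (SE 0.25, adjusted p = 0.0329). The fetal liver gene Afp stood at 1.01 and 3.4 CPM (adjusted p = 0.0687) and Sox9, a factor of biliary and progenitor cells, at 6.31 and 6.55 CPM (adjusted p = 0.956). Markers of cholangiocytes, the cells that line bile ducts, moved with this group: 6 of 13 rose, 8 adjusted over the list alone. Their median was 1.19 (list test adjusted p = 1.09e-07, and 0.187 with an estimated correlation). It was 1.91 with DESeq2 and 1.70 without F/F replicate 3, where the members kept can differ. Cholangiocyte markers shared Krt19, Krt7, Epcam and Sox9 with the stemness list. Others were Tspan8 (2.90, and 2.22 without ΔHep replicate 2), Muc1 (2.07), St14 (1.84) and the water channel Aqp1 (0.60).

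Cell cycle genes were higher in ΔHep in all 30 tested members, with a median log2 fold change of 1.40. Of these, 5 passed, and 22 passed when adjusted over the list alone. The list test gave an adjusted p of 6.59e-16, and an adjusted p = 0.187 with an estimated correlation. Bub1, a kinase of the spindle checkpoint, rose by 3.15 (SE 0.51), Cdc20, an activator of the anaphase-promoting complex, by 2.34 (SE 0.32), Bub1b by 1.95 (SE 0.36), Cdk1, the mitotic kinase, by 1.75 (SE 0.28), and Mcm2, a subunit of the replicative helicase, by 0.94. Levels stayed low: Cdk1 was at 1.28 ± 0.415 CPM in F/F and 4.30 ± 0.296 CPM in ΔHep. Markers of stellate cells (median 1.07) and macrophages (median 0.87) were higher in the same libraries.

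Hepatic β-catenin targets did not pass the list test, with an adjusted p of 0.0663 towards lower values and an adjusted p = 0.665 with an estimated correlation. None of 23 tested members passed with edgeR, over all genes or adjusted over the list alone (0 each). At an unadjusted p below 0.05, 1 was higher and 2 were lower, and DESeq2 called 1, higher, and limma-voom 0. Glul, glutamine synthetase of hepatocytes around the central vein, stood at 1230 ± 204 CPM in F/F and 979 ± 456 CPM in ΔHep (log2 fold change -0.33, adjusted p = 0.628). Cyp2e1, a cytochrome P450 of the same cells, had a log2 fold change of -0.59 (adjusted p = 0.276) and Tbx3, a T-box factor, stood at 54.2 ± 13.2 and 27.1 ± 15.03 CPM (adjusted p = 0.208). The median log2 fold change was -0.10, and single libraries moved it. It was 0.01 without ΔHep replicate 3 (list test adjusted p = 0.717), and -0.38 and -0.39 without ΔHep replicates 1 and 2. Without F/F replicates 1, 2 and 3 it was -0.06, -0.15 and -0.20. The method moved it too, to -0.33 with limma-voom and -0.01 with library totals only. Without F/F replicate 1, F/F replicate 2, ΔHep replicate 1 or ΔHep replicate 2 the list passed, at 0.0368, 0.041, 0.0131 and 0.00277, and without F/F replicate 3 it did not (0.211).

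Mature hepatocyte genes were lower by a small amount as a group. The median log2 fold change of 29 tested members was -0.14, with 22 negative values, and 0 members passed in edgeR, over all genes or adjusted over the list alone. At an unadjusted p below 0.05, 6 members were lower and 0 higher, and DESeq2 called 3 lower and limma-voom 0. The list test gave an adjusted p of 0.00234, and an adjusted p = 0.187 with an estimated correlation, which was -0.0123. Apob, the main protein of lipoprotein particles, had a log2 fold change of -0.07 (adjusted p = 0.893), and Cyp3a11, a drug-metabolising P450, of -0.40 (adjusted p = 0.216). The median was -0.07 without F/F replicate 3, -0.25 without ΔHep replicate 1 and -0.04 with library totals only. Markers of other cell types moved the other way in the same libraries, and are given next.

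Markers of non-hepatocyte cells were higher in ΔHep in 7 lists, counting cholangiocytes. Stellate cell and fibroblast markers had 7 of 22 members that rose and 18 adjusted over the list alone, with a median of 1.07 (adjusted p = 1.8e-15; adjusted p = 0.187 with an estimated correlation). Col6a3 rose from 13.4 ± 4.50 to 52.5 ± 16.7 CPM, Col1a2 from 24.6 ± 7.82 to 75.4 ± 22.7 CPM, the proteoglycan Lum from 9.51 ± 1.16 to 26.8 ± 7.15 CPM and the growth factor receptor Pdgfra from 8.89 ± 2.46 to 21.4 ± 4.57 CPM. Of 22 macrophage and Kupffer cell markers 3 rose, 10 adjusted over the list alone, with a median of 0.87 (adjusted p = 3.69e-12; adjusted p = 0.231 with an estimated correlation), which was 1.5 without F/F replicate 3. They were Gpnmb, the lipid receptor Trem2 (2.63, SE 0.49, and 3.24 without F/F replicate 1) and the monocyte chemokine receptor Ccr2 (2.22, SE 0.38). Among dendritic cell and MHC class II genes 2 of 12 rose, 5 adjusted over the list alone, with a median of 1.25 (adjusted p = 8.83e-08; adjusted p = 0.187 with an estimated correlation); Cd74, the invariant chain, went from 48.9 ± 9.85 to 119 ± 21.7 CPM, and the integrin Itgax rose by 2.03. Of 21 endothelial markers Eng, the endoglin co-receptor, rose by 0.73 (SE 0.14), with 6 higher adjusted over the list alone and a median of 0.59 (adjusted p = 3.67e-08; adjusted p = 0.303 with an estimated correlation). T and NK cell markers had a median of 1.59 over 17 members (adjusted p = 2.58e-06; adjusted p = 0.269 with an estimated correlation), with 0 past the threshold in edgeR, 6 adjusted over the list alone and 10 at an unadjusted p below 0.05 (DESeq2 3, limma-voom 0); Ccl5 stood at 0.850 and 4.76 CPM (adjusted p = 0.0667) and Il2rb at 2.40 and 5.49 CPM (adjusted p = 0.0673). B and plasma cell markers had a median of 1.43 over 9 members (adjusted p = 0.000366; adjusted p = 0.303 with an estimated correlation), with 0 past the threshold in edgeR, 2 adjusted over the list alone and 6 at an unadjusted p below 0.05 (DESeq2 2, limma-voom 0); Jchain stood at 5.65 and 14.6 CPM (adjusted p = 0.0649) and Bank1 at 1.84 and 3.36 CPM (adjusted p = 0.192). ΔHep replicate 3 had a list score of 2.36 for B and plasma cell markers, against 0.96 and 1.12 in the other ΔHep libraries. Without it the median of that list was 0.80, over the members kept in that fit.

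In the epithelial-mesenchymal transition list, which was higher beside the fibroblast markers (median 1.07), 4 of 19 members rose, 6 adjusted over the list alone, with a median of 0.54 (adjusted p = 1.09e-07; adjusted p = 0.231 with an estimated correlation). Vim, the intermediate filament of mesenchymal cells, rose from 28.4 ± 5.90 to 69.1 ± 15.7 CPM, Tgfbi, a matrix protein, by 0.89 (SE 0.15), and Mmp2, a gelatinase, by 1.95 (SE 0.34). The Notch and Hippo list held receptors, ligands and effectors of these pathways beside their targets, so it does not read out target activity alone. Its median was 0.51 over 16 members (adjusted p = 0.00143, and 0.231 with an estimated correlation). In edgeR 0 passed the threshold, and 5 passed adjusted over the list alone. At an unadjusted p below 0.05, 8 were higher and 1 lower, and DESeq2 called 4 higher and limma-voom 0. Notch2 had a log2 fold change of 0.24 (adjusted p = 0.419) and the Hippo effector Yap1 of -0.28 (adjusted p = 0.178). Cholangiocyte (median 1.19), stellate cell (1.07) and macrophage markers (0.87) were higher in the same libraries, beside the Notch and Hippo list and the next. Among imprinted and oncofetal genes 2 of 14 rose, 7 adjusted over the list alone, with a median of 1.02 (adjusted p = 2.75e-05; adjusted p = 0.187 with an estimated correlation): Ly6d, given above, and Scd2, a stearoyl-CoA desaturase, by 1.37 (SE 0.27).

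Interferon response genes were higher in ΔHep, where markers of immune cells were higher too. Of 24 members 3 rose, 16 adjusted over the list alone, 23 had positive fold changes, and the median was 0.70 (adjusted p = 3.07e-11; adjusted p = 0.269 with an estimated correlation). Ifi44 rose from 4.30 ± 1.55 to 15.1 ± 2.94 CPM, Oasl2 from 5.00 ± 1.66 to 15.9 ± 4.28 CPM and Ifit3 from 8.48 ± 0.856 to 17.6 ± 4.09 CPM, all of them induced by type I interferon.

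Genes of the endoplasmic reticulum stress response were lower as a group, with a median of -0.51 over 18 members (adjusted p = 1.37e-05; adjusted p = 0.187 with an estimated correlation). None passed with edgeR over all genes (0), 1 was lower adjusted over the list alone, and at an unadjusted p below 0.05 there were 9 lower and 1 higher (DESeq2 4 lower, limma-voom 0). The chaperone Hspa5 stood at 1155 and 723 CPM (log2 fold change -0.68, adjusted p = 0.136) and Hsp90b1 at 1125 and 829 CPM (-0.44, adjusted p = 0.249). Markers of stellate cells (median 1.07), T and NK cells (1.59) and cholangiocytes (1.19) were higher in the same libraries, beside this list and the next. Male-biased liver genes were also lower, with a median of -0.38 over 16 members (adjusted p = 0.000384; adjusted p = 0.303 with an estimated correlation), 0 past the threshold in edgeR, 1 lower adjusted over the list alone and 6 lower at an unadjusted p below 0.05 (DESeq2 1, limma-voom 0). The list scores of the groups overlapped: ΔHep replicates 1, 2 and 3 lay at -0.72, -0.09 and -0.77, and F/F replicates 1, 2 and 3 at -0.11, -0.25 and 0.34. The median was -0.24 without F/F replicate 3 and -0.58 without ΔHep replicate 2. Serpina1e and Cyp2d9, their most abundant members, had log2 fold changes of 0.28 (adjusted p = 0.64) and -0.32 (adjusted p = 0.362). Female-biased genes did not pass (median 0.66, list test adjusted p = 0.214). Their median was 0.24 without F/F replicate 3 or ΔHep replicate 1 and 0.23 with DESeq2, where the members kept can also differ. Of this list Cyp2a4, a steroid hydroxylase, rose by 2.84 (SE 0.53, adjusted p = 0.0449). Its close paralog Cyp2a5 (-0.14, adjusted p = 0.791) can share reads with it, so both values are uncertain. ΔHep replicate 3 held most of the Cyp2a4 signal (196 CPM against 49.6 and 65.9 CPM in ΔHep replicates 1 and 2); without it the log2 fold change was 1.99 and did not pass (adjusted p = 0.0924). Several other settings ended the call too, among them robust moderation, limma-voom and leaving out F/F replicate 1, F/F replicate 2 or ΔHep replicate 2.

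**Figure D3:**
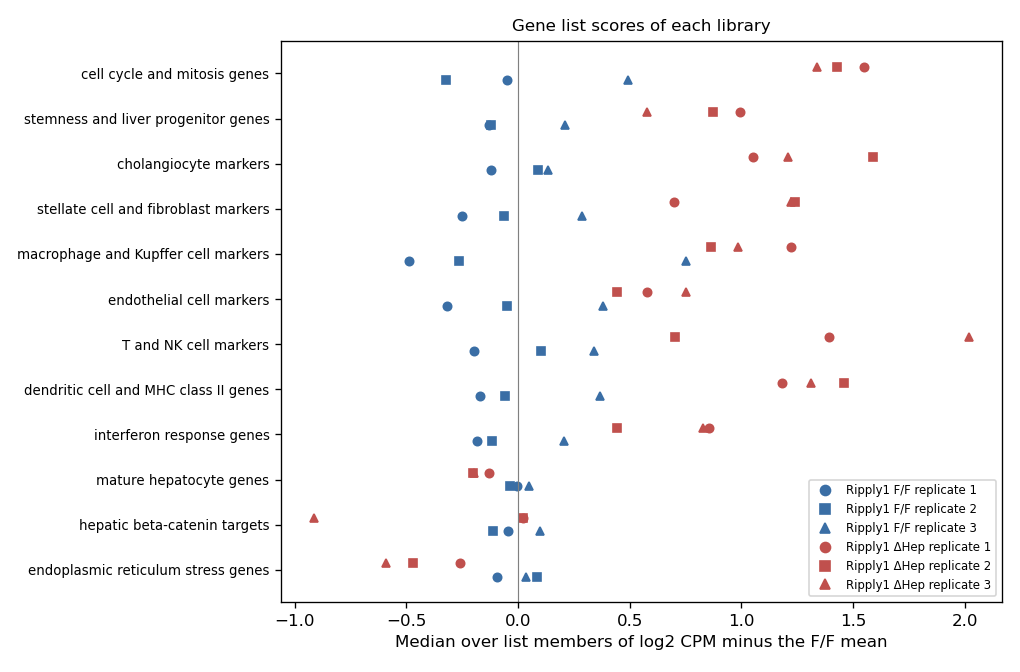
Score of each library for 12 gene lists, the median over list members of log2 CPM minus the F/F mean of the member (horizontal axis, log2 units); each point is a library, coloured by genotype and shaped by replicate. ΔHep libraries lie at 1.34 to 1.55 for cell cycle genes, and ΔHep replicate 3 stands apart at -0.91 for β-catenin targets.

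The other lists did not pass the list test. Phenobarbital and CAR-induced genes had a median of -0.17 (adjusted p = 0.0869), periportal genes of -0.07 (adjusted p = 0.457; Pck1 0.18, Pigr -0.28) with a mean of 0.02, and fatty acid oxidation genes of -0.09 (adjusted p = 0.528) with a mean of 0.21, so median and mean differed in sign in the last pair. Fatty acid synthesis genes had a median of 0.30 (adjusted p = 0.133), cholesterol synthesis genes of 0.19 (adjusted p = 0.217; Sc5d 0.09) and glycolysis genes of 0.02 (adjusted p = 0.338; Ldha -0.08, Tpi1 -0.01). Acute phase genes had a positive median of 0.11 and a test towards lower values (adjusted p = 0.997; Hpx 0.35, Fga -0.05). Medians were 0.27 for p53 targets (adjusted p = 0.243; Trp53inp1 0.32, Ei24 -0.11), 0.30 for NRF2 and oxidative stress genes (adjusted p = 0.133; Ephx1 -0.04, Gclc 0.37) and 0.16 for immediate early genes (adjusted p = 0.13), of which Egr1 (1.55, SE 0.30) and Klf6 (0.97, SE 0.15) rose. RIPPLY and T-box axis genes had a median of -0.12 over 9 members (adjusted p = 0.701), with the co-repressor Tle1 at 0.29 (adjusted p = 0.232). Neutrophil markers had a median of 1.23 over 3 members (adjusted p = 0.0621; Csf3r 1.23, S100a9 1.78), erythroid markers of 1.05 (adjusted p = 0.528; Alas2 -0.15, Hba-a1 0.95) and the 2 pancreatic acinar genes of 0.06 with a test towards lower values (adjusted p = 0.314; Cela1 -0.74, Cela2a 0.85). Single libraries turned the sign of several of these medians: erythroid markers stood at -0.12 without ΔHep replicate 3, acute phase genes at -0.28 and periportal and fatty acid oxidation genes at 0.06 and 0.10 without ΔHep replicate 2, phenobarbital-induced and T-box axis genes at 0.02 and 0.04 without F/F replicate 1, and immediate early genes at -0.02 without ΔHep replicate 1. Fatty acid oxidation and T-box axis genes also turned, to 0.02 each, without F/F replicates 2 and 3 respectively. Glycolysis genes stood at -0.03 and -0.02 without F/F replicate 3 and ΔHep replicate 3, and acinar genes were negative without F/F replicate 2 or 3 or ΔHep replicate 2 or 3. With library totals only, periportal genes stood at 0.02. Other medians kept their sign but moved. Fatty acid synthesis genes went to 0.09 and 0.46 without ΔHep replicates 3 and 2. Cholesterol synthesis genes went to 0.08 and 0.50 without ΔHep replicate 2 and F/F replicate 3. Medians were 0.12 for p53 targets without F/F replicate 2, 0.17 for NRF2 genes without ΔHep replicate 3 and 2.30 for neutrophil markers without ΔHep replicate 1. In lists with members near the filter, such as the erythroid, T-box axis and neutrophil lists, these moves and turns of sign may also reflect changed members. None of the 13 mitochondrially encoded mRNAs was analysed here (0 tested).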

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

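The alternatives below were fixed before the data were examined, except fry and the left-out libraries for the 28 secondary lists, which were chosen after seeing the data. Ripply1 kept its direction throughout, with log2 ratios from -3.17 to -3.69 without single libraries, and passed with DESeq2 (-3.36). Of 244 genes, 220 higher and 24 lower, the count moved to 644 (615 higher) with library totals only, which shifted the median fold change of all genes by 0.0942, to 1304 (1075 higher, 229 lower) with DESeq2 and to 88 (76 higher, 12 lower) with limma-voom; the cause was not tested. A fold threshold of at least 1 on the log2 scale left 204, of which 13 were lower. Without single libraries the count ranged from 1 to 1246, with 0 to 1022 higher and 1 to 224 lower. Other scaling, other filters and robust moderation gave 226 to 273. A replicate block gave 236, of which 137 were shared, and 21 named genes no longer passed under it, Cyp2a4 among them. Correlations of libraries with the same number were 0.113, -0.0689 and -0.00898. They gave no sign that the numbers pair the samples, and so few libraries cannot exclude it. Of 93 named genes tested 55 passed and kept their sign wherever tested, while some that did not pass changed sign, Apob and Glul among them; of the 55, 34 were lost with limma-voom and between 0 and 54 without single libraries. List tests lost their calls with an estimated correlation for stemness (0.231), mature hepatocyte (0.187) and cell cycle genes (0.187). With fry, which tests a list against no change, these lists kept them narrowly (adjusted p = 0.0488, 0.0429 and 0.0429). The β-catenin list did not pass with fry (adjusted p = 0.543). The estimated correlations were 0.224, -0.0123 and 0.205. That of mature hepatocyte genes lay below the preset 0.01, so correlated members do not account for that lost call. The list p of these genes before adjustment still rose from 0.00117 to 0.0214. A call lost with an estimated correlation is therefore no evidence by itself that the members vary together. Without single libraries the adjusted p of these list tests, in the same order, ranged from 2.06e-10 to 9.42e-06, from 0.000607 to 0.0213 and from 1.13e-17 to 3.63e-12. For β-catenin targets it ranged from 0.00277 to 0.717. Of the secondary lists 13 passed, 0 with an estimated correlation, 6 with fry and 13 to 19 without single libraries. Tbx19 was not analysed here, so its alternatives were not run. Depth limits the fold changes of genes near 1 CPM and of Ripply1.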

Other observations

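All tests of explanations in this part were chosen after the results were seen, the counts over other splits of the libraries included. Dkk4, a secreted Wnt inhibitor that is itself a target of β-catenin, fell outside the naming rule because of its low level and was chosen after its values were seen. It held 12, 16 and 27 counts in the F/F libraries and 1, 2 and 0 in the ΔHep libraries, a ratio of pooled counts of 22.1 (exact 95% interval 7.17 to 110) and an adjusted p of 0.0449. Ccnd1, the cyclin of the G1 phase and the only β-catenin list member above a log2 fold change of 1, stood at 27.0 ± 14.3 CPM in F/F and 81.1 ± 32.8 CPM in ΔHep (log2 fold change 1.59, adjusted p = 0.07). Targets that mark hepatocytes around the central vein were lowest in ΔHep replicate 3: Glul was at 453 CPM there and at 1223 and 1261 CPM in the other ΔHep libraries, and Oat at 195 CPM against 1016 and 707 CPM. ΔHep replicate 2 held 875 CPM of the acute phase gene Saa1, against 84.5 and 41.7 CPM in the other ΔHep libraries. Cyp2b10, the marker of phenobarbital induction, was at 12.03, 10.69 and 13.16 CPM in F/F and at 37.03, 2.02 and 11.7 CPM in ΔHep replicates 1, 2 and 3.

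Few genes passed when a library other than F/F replicate 3 or ΔHep replicate 1 was left out, and their names were read after the result. Serpine2 passed without each single library. Without F/F replicate 1, Ntrk2, a neurotrophin receptor, passed beside it (log2 fold change 2.79, adjusted p = 0.0349). Gldn and Gpnmb passed without ΔHep replicate 2, together with Pydc4, and without ΔHep replicate 3, together with Htra3 and Sparcl1, with adjusted p from 0.0246 to 0.036. The real split of the 6 libraries called 244 genes, 220 of them in one direction and 24 in the other, and the highest count of the other 9 splits was 0 on each with edgeR. At an unadjusted p below 0.05 the real split had 3069 genes and the others 111 to 1430. For the lists, the real split put 16 past the test at the preset correlation and the highest other split 20, with 4 of 10 splits at 16 or more. List p before adjustment was 0.0373 for β-catenin targets (3.82e-05 in the most extreme other split; 9 of 10 splits as small), 9.25e-08 for stemness genes (1.83e-06; 1 of 10), 0.00117 for mature hepatocyte genes (0.000332; 2 of 10) and 2.06e-17 for cell cycle genes (1.21e-07; 1 of 10). With 10 splits, a share under 0.05 cannot be reached. The test at the preset correlation calls many lists in splits that mix the genotypes, and the p with an estimated correlation stands beside each call. The mixed splits hold the genotypes in unequal shares, so part of any genotype difference stays between their groups. The rest lies inside the groups and widens the spread of genes. Neither their 0 genes nor their list calls therefore measure chance alone.

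Markers of 7 non-hepatocyte lists were higher in ΔHep. A uniformly lower share of hepatocyte RNA would raise all of them by the same factor only if hepatocytes expressed none of these genes. Of 6 lists compared with the endothelial list, 4 shifted further by more than 2 standard errors with ranges that did not overlap: stellate cell markers by 0.47 ± 0.20 (SE, log2 units, n = 3 each), T and NK cell markers by 0.70 ± 0.30, dendritic cell and MHC class II genes by 0.69 ± 0.16 and cholangiocyte markers by 0.66 ± 0.27. Macrophage markers (0.44 ± 0.22) and B cell markers (0.83 ± 0.44) did not separate. All 4 were set against the same endothelial list, without adjustment over the 6 lists. A bound of 2 standard errors is lenient with n = 3 each. The stellate cell, T and NK cell and cholangiocyte shifts passed it only narrowly. Some gaps were narrow, as between ΔHep replicate 1 (0.12) and F/F replicate 1 (0.066) for stellate cell markers. Dendritic cell and MHC class II genes lay at 0.56 to 1.02 in ΔHep and at -0.0121 to 0.147 in F/F. A shift beyond that of endothelial markers was thus clearest for dendritic cell and MHC class II genes. It stays uncertain for the stellate cell, T and NK cell and cholangiocyte lists. The comparison does not decide whether the share of hepatocyte RNA was uniformly lower. Members that hepatocytes also express would shift less under that explanation, the reference was shared, and n was 3. A changed mix of other cells in the tumours, their uneven carry-over into the isolation, and expression of such genes by tumour hepatocytes stay open, and the genotype remains untested against them.

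F/F replicate 3 lay towards the ΔHep libraries on the first principal component (50.2% of variance), at -13.0 against -52.1 and -45.7 for the other F/F libraries and 26.5 to 48.0 for ΔHep, and leaving it out raised the count of genes from 244 to 1246. A mislabelled ΔHep library would hold about 1.07 Ripply1 counts at this depth, whereas it held 12 (exact Poisson p = 1.75e-09), which argues against that explanation. More RNA of macrophages and endothelial cells may contribute: against the mean of the other F/F libraries the macrophage list had a median log2 ratio of 1.02 and the endothelial list of 0.54, both at percentile 100 of 10000 random lists matched on expression. Clec4f, a Kupffer cell lectin, was at 169 CPM there, at 69.9 and 78.5 CPM in the other F/F libraries and at 189, 131 and 141 CPM in ΔHep, while Gpnmb stayed at 0.466 CPM and Krt19 at 1.00 CPM. Cell cycle (0.45), acute phase (0.46) and stellate cell genes (0.34) also lay at percentile 100. So did, among genes of hepatocytes, cholesterol synthesis (0.62) and male-biased genes (0.46). Female-biased (-0.74), phenobarbital-induced (-0.37) and fatty acid oxidation genes (-0.22) lay at percentile 0, so the library differed in more than these cells. Members of the random lists were drawn independently of each other. Members of the real lists can vary together, with estimated correlations of 0.476 for macrophage and 0.581 for endothelial markers. The percentiles can therefore overstate how unusual these lists were.

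The rise of stemness and progenitor genes may come from tumour hepatocytes or from other cells, biliary cells included. The 17 members held by no cell type list had a median log2 fold change of 0.63, with 14 positive and 2 past the threshold, Prom1 and Cd24a, and the 4 members shared with such lists a median of 1.57. Tested alone, the 17 members gave a list p of 1.48e-05 at the preset correlation and of 0.0896 with an estimated one. The sources cannot be told apart for this list, because the members vary together across 6 libraries and bulk RNA does not assign a transcript to a cell.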
